A study of Homo sapiens with 4 samples.

How the data were processed

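RNA sequencing was done on 2 human liver cancer cell lines, HepG2 and Huh7, each untreated and treated for 24 h with RSL3@O2-ICG NBS together with low-frequency ultrasound, per the labels. The 4 groups hold 1 library each. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made from 1 µg of it with an Illumina TruSeq RNA kit. The labels do not say how transcripts were selected from the total RNA, whether strand was kept, or what NBS stands for.

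The authors deposited 1 table of FPKM (fragments per kilobase of transcript and 1000000 fragments) per coding gene and 1 table of FPKM per long noncoding RNA transcript, with 1 column per library, per the file headers. Every column of per-library values was used. The submitters' processing notes name Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, Cuffdiff 2.1.1, Picard 1.96, SAMtools 0.1.18 and GATK, without their roles or order. The genome build and annotation are not given in the sources used here. Of the 19739 genes of the coding table, 19664 have an identifier in GENCODE 29, and the listed position of 19632 of these (99.84%) overlaps the GENCODE 29 gene, with 18037 agreeing within 1000 bases at both ends. Positions are therefore GRCh38 coordinates by this match. The long noncoding table lists 29119 transcripts of 17699 genes, some under assembler identifiers that no annotation here resolves.

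The authors also deposited enrichment tables for their own comparisons of treated with untreated cells, with p-values and corrected p-values per Gene Ontology term and per KEGG pathway, per the file headers. The KEGG header names a hypergeometric or Fisher test with Benjamini-Hochberg correction. How the authors chose the genes that entered these tables is not given in the sources used here. The meaning of CAD in the Gene Ontology file is not stated.

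FPKM values are not counts, so no count model was fitted. Depth was inferred from low values: for genes with 1 annotated transcript, FPKM multiplied by transcript length in kilobases fell most often at a fixed step, taken as 1 fragment. The steps give 25700000 and 23200000 fragments for the untreated and treated libraries labelled HepG2, and 26400000 and 22900000 for Huh7. A transcript of 1 kb at 1 FPKM then rests on 26, 23, 26 and 23 fragments, with exact 95% Poisson intervals of 17.0 to 38.1 for 26 and 14.6 to 34.5 for 23. These intervals cover counting error only.

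For each gene and line the ratio log2((treated FPKM + 1)/(untreated FPKM + 1)) was computed. Genes with FPKM of 1 or more in at least 1 of the 2 libraries of a line were considered, and those at least 2-fold higher or lower were counted. With 1 library per group there is no test within a line. A fold on this scale understates the change of genes with low FPKM. Agreement of the lines was described by Pearson and Spearman correlations across genes and by the overlap of the counted genes, beside the overlap of independent lists of those sizes. The only test across libraries was limma (3.58.1, R 4.3.3) with a mean-variance trend on log2(FPKM + 1) of the 4 libraries, with cell line as a block and treatment as the tested term, over genes with FPKM of 1 or more in at least 1 library. It has 1 residual degree of freedom, and its adjusted p (Benjamini-Hochberg, threshold 0.05) asks whether both lines responded alike, not whether repeat cultures would. The pairing of libraries by cell line comes from the labels.

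A set of 30 gene lists was fixed before the data were examined, as were the rules of size, the test and the alternatives named here. They cover ferroptosis suppressors and drivers, NRF2 targets, the ATF4 integrated stress response, endoplasmic reticulum chaperones, the heat shock response, mitosis, DNA replication, replication-dependent histones, cholesterol synthesis, fatty acid synthesis and oxidation, the hypoxia response, hepatocyte secreted proteins and metabolism, AHR targets, NF-kB and inflammation, interferon-stimulated genes, immediate early genes, metallothioneins, mitochondrially encoded genes, nuclear respiratory chain genes, the BCL2 family and caspases, autophagy and lysosome, ribosomal proteins, mesenchymal transition and matrix, and markers of fibroblasts and stellate cells, endothelium and blood cells. Of the 30 lists, 1 is not reported here, though the numbers of lists outside the random range include it, nor are some of the genes the rules name. Older symbols were accepted. For each list and line the median log2 ratio of the measured members was placed as a percentile among 10000 random lists of the same size, matched on 10 deciles of mean expression (seed 11). A median under the 2.5 or over the 97.5 percentile is said to lie outside the random range. Percentiles describe these libraries and are not p-values.

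The genes named were set by rule: per line the 10 highest and 10 lowest ratios, the 10 higher and 10 lower in both lines with the largest smaller ratio, up to 4 members of each list with the largest ratio in either line, genes of ferroptosis and iron (GPX4, SLC7A11, ACSL4, AIFM2, TFRC, FTH1, FTL, HMOX1, CHAC1, PTGS2 and NFE2L2), the 5 highest and 5 lowest long noncoding transcripts per line, and the 10 largest differences between the lines. Some were left out for length. Where 5 or fewer members of a list passed 2-fold, most are named, and those outside the rule were chosen after their values were seen, as is any other gene where this is said.

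Genes were called uncertain where 20% or more of their exonic bases overlap another coding gene in GENCODE 29, or where 50% or more of the longest transcript matches another gene's at 97% identity (BLAST+ 2.17.0). Overlap was found for 7.0% of the genes and such copies for 5.6%. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.

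The limma fit and the 2-fold rule on coding genes were tested on simulated data, and the list percentile on random lists. No other step was tested so. With 200 of 13030 genes changed alike in both lines, limma recovered 49.5% of those changed by 1 on the log2 scale (4 false calls), 96.0% of those changed by 1.5 (6 false) and 100.0% of those changed by 2 (11 false). Simulated noise followed the mean-variance trend, with no spread between genes of like level. Recovery in the real data may therefore be lower. For counting noise at the inferred depth, the 2-fold rule found 69 of 100 genes changed 2.5-fold in the libraries labelled HepG2 and 68 of 100 in Huh7. For a 4-fold change it found 93 and 97 of 100. No unchanged gene passed among 11023 and 11294. Of 200 lists of 25 genes drawn at random from the real ratios under the HepG2 label, 9 lay outside the random range. Such lists are random by construction, so this count does not cover lists of genes that vary together. A list so drawn and raised by 0.5 lay at percentile 100.0.

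The alternatives tried were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, rescaling each library to a sum of 1000000, median-ratio size factors, 1.5-fold and 4-fold rules, the mean in place of the median of a list, limma without the block or without the trend, and a corrected p under 0.01 for the authors' terms. Counts within 1.5 times of each other were treated as unmoved.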

Results

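Transcript levels were measured in 2 human liver cancer cell lines, HepG2 and Huh7, before and after a 24 h treatment with RSL3@O2-ICG NBS and low-frequency ultrasound. RSL3 binds and inhibits GPX4, the selenoenzyme that reduces lipid hydroperoxides, and is a standard inducer of ferroptosis, the iron-dependent cell death that follows lipid peroxidation. Each of the 4 groups held 1 library, so no value has a replicate, an SD or a p within a line, and no difference between the lines was tested. No sample analysed here received ultrasound alone, the carrier alone or RSL3 alone. The inferred depth was 22900000 to 26400000 fragments per library, and 11156 to 11715 coding genes reached 1 FPKM. Across 13030 genes, log2(FPKM + 1) correlated at r = 0.954 between treated and untreated libraries labelled HepG2 (rho = 0.948), at r = 0.963 in Huh7 (rho = 0.957), and at r = 0.723 to 0.74 between lines; genes are not independent replicates.

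The libraries labelled HepG2 lacked the transcripts of secreted liver proteins, which both Huh7 libraries had. ALB, the gene of serum albumin, was listed at 0 in both libraries labelled HepG2 and at 883 FPKM in untreated and 711 FPKM in treated Huh7. AFP, the fetal counterpart of albumin, stood at 0.0154 and 0 FPKM against 178 and 88.2 in Huh7. The fibrinogen chain FGA was listed at 0 in both against 295 and 225 FPKM, and TF, which encodes transferrin, stood at 0 and 0.0125 against 133 and 103 FPKM. Of 33 hepatocyte secreted proteins, 30 and 28 were below 1 FPKM in the untreated and treated libraries labelled HepG2, and 4 in each Huh7 library. The hepatocyte regulators HNF4A (0.449 and 0.166 FPKM) and FOXA2 (listed at 0) were also low there, against 12.3 and 8.95 FPKM and 37.6 and 41.9 FPKM in Huh7. The housekeeping genes GAPDH (4319.7, 3716, 3919.1 and 3623.2 FPKM) and ACTB (1506.2, 1298.6, 1275.9 and 1007.9 FPKM) were read in all 4 libraries. Other genes, chosen after their values were seen, were high there: FOLR1, a folate receptor, stood at 1605.8 and 3128.6 FPKM in the libraries labelled HepG2 against 0.122 and 0.513 in Huh7. The placental alkaline phosphatase ALPP stood at 88.9 and 23.6 FPKM, and MSLN, which encodes mesothelin, at 32.3 and 47.1 FPKM against 0 in both Huh7 libraries. HepG2 is known as a line that secretes albumin, fibrinogen and transferrin, so these libraries are named by their label throughout, and every direction drawn from them holds for cells so labelled.

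**Figure D1:**
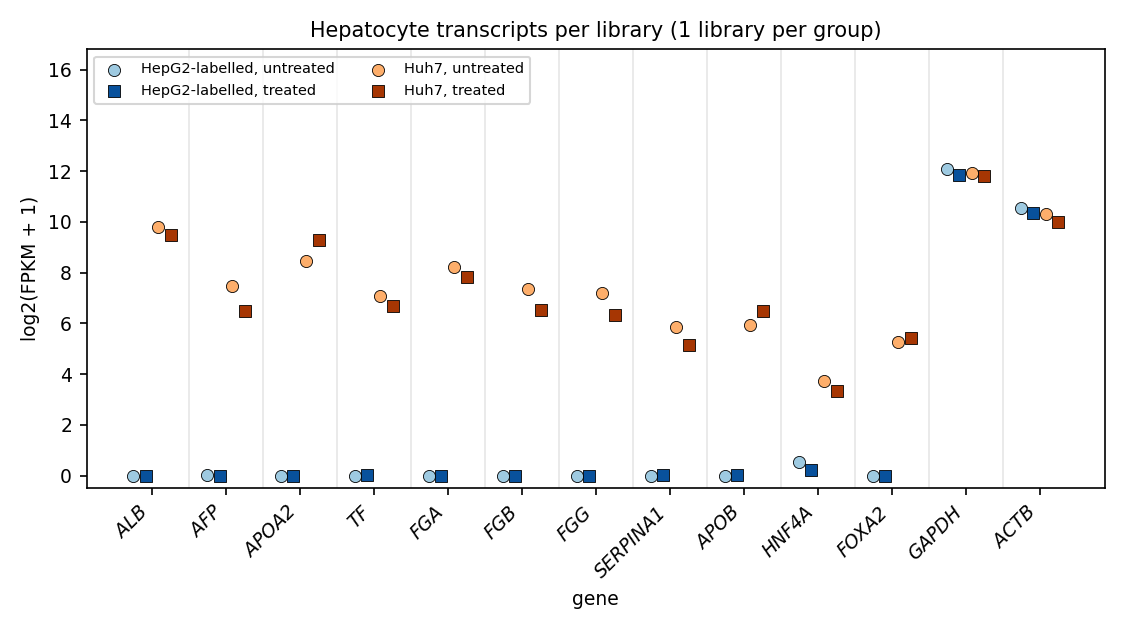
Level of liver transcripts and of the housekeeping genes GAPDH and ACTB in each of the 4 libraries, as log2(FPKM + 1), 1 point per library. ALB, FGA and FOXA2 sit at 0 in both libraries labelled HepG2 and at 37.6 FPKM or more in both Huh7 libraries, while GAPDH lies between 3623.2 and 4319.7 FPKM in all 4.

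The treatment targets ferroptosis, and the genes of iron storage were higher after it in both lines while GPX4 transcript was not. FTL, the ferritin light chain (ENSG00000087086; chromosome 19, 48965309 to 48966879), stood at 842 FPKM untreated and 2514.1 FPKM treated in the libraries labelled HepG2, and at 5785.7 and 18301.6 FPKM in Huh7, where it became the most abundant coding transcript. These are ratios of 2.98-fold and 3.16-fold on the log2(FPKM + 1) scale, which understates the change of low genes. FTH1, the ferritin heavy chain, was 2.09-fold and 3.48-fold higher. It is called uncertain because 62.4% of its exonic bases overlap BEST1, but BEST1 was read far lower. BEST1 stood at 13.7 and 73.2 FPKM in the libraries labelled HepG2, against 3078 and 6428.4 FPKM for FTH1. In Huh7 BEST1 stood at 11.6 and 11.8 FPKM, against 659 and 2295.7 FPKM for FTH1. HMOX1, which frees iron from haem, went from 22.7 to 81.0 FPKM and from 21.0 to 55.6 FPKM. TFRC, the transferrin receptor that brings iron into the cell, was lower in both lines, at 137 against 78.7 FPKM and 60.1 against 34 FPKM, short of 2-fold. GPX4 (ENSG00000167468; chromosome 19, 1103926 to 1106791) stood at 167 and 100 FPKM in the libraries labelled HepG2 and at 290 and 255 FPKM in Huh7.

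CHAC1, an enzyme that degrades glutathione and a common transcript marker of ferroptosis, went from 1.34 to 24.7 FPKM in the libraries labelled HepG2 and from 2.08 to 6.73 FPKM in Huh7. SLC7A11, the cystine importer that feeds glutathione synthesis, stood at 13.3 and 14.4 FPKM, and at 2.29 and 5.36 FPKM in Huh7. Its partner chain SLC3A2 was 2.36-fold higher in Huh7 (117 and 277 FPKM) and 1.15-fold in the libraries labelled HepG2. ACSL4, which loads polyunsaturated fatty acids into lipids, had log2 ratios of 0.12 and 0.37, and AIFM2, a quinone reductase that limits lipid peroxidation, of 0.19 and −0.33. PTGS2, another marker used for ferroptosis, was lower in the libraries labelled HepG2 (10.1 and 3.86 FPKM) and under 1 FPKM in Huh7. NFE2L2, which encodes NRF2, had log2 ratios of −0.85 and 0.45. Of the ferroptosis suppressors, 4 of 27 measured members were at least 2-fold higher in the libraries labelled HepG2 (median log2 ratio 0.21, percentile 96.1) and 4 of 26 in Huh7 (0.27, percentile 99.41), with none lower. By the mean of members, the list in the libraries labelled HepG2 also lay outside the random range (0.35, percentile 99.64). Those higher were CBS, FTL, FTH1 and GCH1 in the libraries labelled HepG2 and FTH1, FTL, SLC3A2 and GCLC in Huh7. CBS, of the transsulfuration pathway to cysteine, stood at 7.26 and 30.2 FPKM in the former. It is uncertain because CBSL is an identical copy, though CBSL was listed at 0 in both libraries labelled HepG2. The ferroptosis drivers lay inside the random range in both lines. Under the HepG2 label the median was 0.07 (percentile 75.17), with 3 of 26 higher and 1 lower. In Huh7 it was −0.02 (percentile 45.53), with CHAC1 alone of 25 higher, but 2 of 25 with a pseudocount of 0.1 or after rescaling. In the libraries labelled HepG2 the higher members were CHAC1 and the lipoxygenases ALOX5 (0.471 and 2.27 FPKM) and ALOXE3 (0.39 and 1.85 FPKM). Both lipoxygenases were near the floor, and at a minimum of 5 FPKM 1 of 24 drivers was higher. The lower one was AGPS, of ether lipid synthesis, at 18.3 and 7.49 FPKM.

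**Figure D2:**
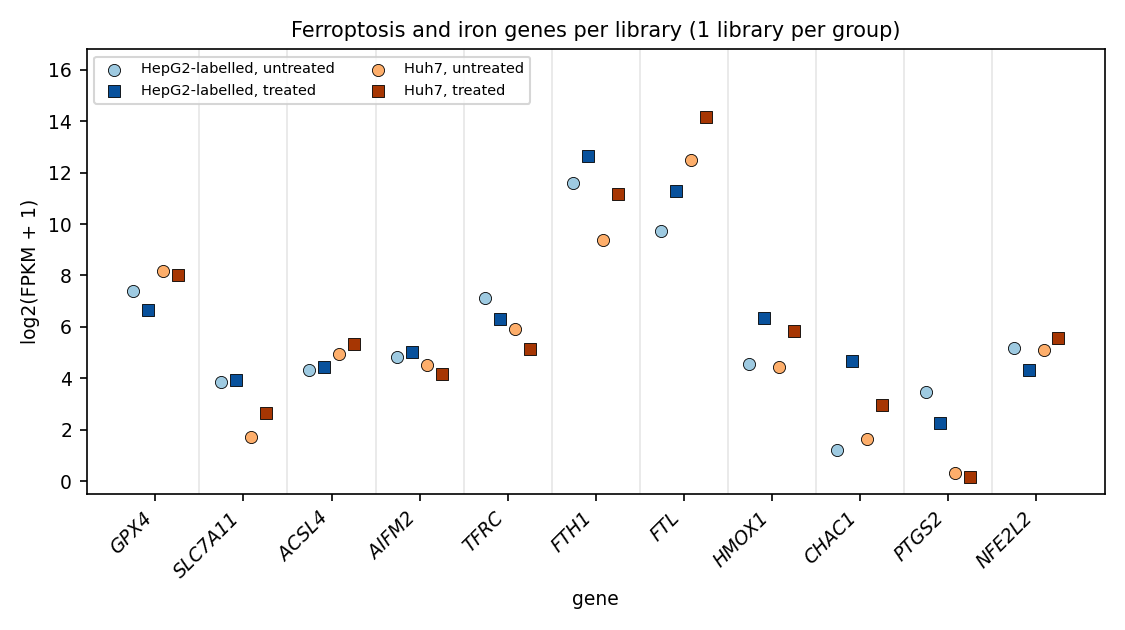
Level of 11 genes of ferroptosis and iron handling in each of the 4 libraries, as log2(FPKM + 1), 1 point per library. FTL, FTH1, HMOX1 and CHAC1 are higher and TFRC lower in the treated library of both lines, and GPX4 stands at 100 FPKM or more in all 4 libraries.

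Treated cells labelled HepG2 had higher amino acid stress genes and lower histone and replication genes. GDF15, a secreted stress cytokine, went from 24.2 to 449 FPKM. ASNS, which makes asparagine, went from 27.4 to 162 FPKM. HIST2H2AC, a replication-dependent H2A gene, went from 968 to 10.8 FPKM, the lowest ratio of that line. Its log2 ratio of −6.36 is not typical of its list, whose median was −0.93, and in Huh7 it stood at 698 and 580 FPKM. Of the 33 measured members of the ATF4 integrated stress response, the programme switched on by amino acid shortage and protein stress, 20 were at least 2-fold higher and none lower (median log2 ratio 1.33, percentile 100).

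In the BCL2 family and caspases of that line, 2 of 21 were higher, the BH3-only genes BBC3 (3.47 and 9.44 FPKM) and HRK (0.324 and 3.81 FPKM), with a median of 0.57 at percentile 99.9. The cyclin-dependent kinase inhibitor CDKN1A stood at 31.6 and 162 FPKM, and SESN2 of the ATF4 list at 4.43 and 28.6 FPKM. Immediate early genes, which follow growth factor and stress signals, had 7 of 18 higher (median 0.84, percentile 100), led by IER3 (12.7 and 61.8 FPKM) and FOSL1 (14.4 and 52.5 FPKM). Endoplasmic reticulum chaperones had a median of 0.35 (percentile 99.81) with 2 of 21 higher, the stress sensor ERN1 (2.1 and 6.27 FPKM) and the cochaperone DNAJB9 (6.43 and 15.0 FPKM). The heat shock response lay inside the random range (−0.00, percentile 56.9; 0.04 after rescaling each library to 1 sum), although 3 of 20 were higher, HSPA6 and the near-identical pair HSPA1A and HSPA1B. HSPA6 stood at 0.401 and 4.91 FPKM and HSPA1A at 65.8 and 162 FPKM.

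Autophagy and lysosome genes had 5 of 28 higher under that label (median 0.51, percentile 100), namely ATG2A, CTSL, WIPI1 (uncertain, as 24.3% overlaps ARSG), the lysosomal sialidase NEU1 (23.4 and 65.9 FPKM) and the protease CTSB (21.5 and 58.3 FPKM). Cholesterol synthesis had 5 of 25 higher (0.45, percentile 99.99), among them MSMO1, SC5D, IDI1 of the isoprenoid pathway (23.5 and 64.0 FPKM) and HMGCS1 (40.4 and 92.2 FPKM). Fatty acid synthesis had 1 of 16 higher, the acetate-activating enzyme ACSS2 at 26.9 and 91.6 FPKM (0.33, percentile 98.64; 0.23, percentile 94.3, with no filter on low values). Fatty acid oxidation lay inside the random range (0.23, percentile 90.62), with 3 of 18 higher, ANGPTL4, ACADS and the lipid droplet gene PLIN2 at 16.9 and 58.4 FPKM. NRF2 targets, the antioxidant programme, had 5 of 30 higher, FTL, FTH1, HMOX1, ABCC3 and BLVRB (0.15, percentile 98.17; percentile 97.39 with no filter). Of 3 measured metallothioneins, MT2A was higher at 89.3 and 219 FPKM (0.88, percentile 99.39; 0.0, percentile 49.29, over all 9 with no filter).

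Histone, replication and respiratory genes were lower in cells labelled HepG2. Replication-dependent histones had 10 of 28 lower and none higher (median −0.93, percentile 0.0). Their messengers lack the usual poly(A) tail, and the labels do not say how RNA was selected. DNA replication genes had a median of −0.45 (percentile 0.0) with only CCNE2 of 31 lower by 2-fold, uncertain as 37.0% overlaps INTS8, and PCNA, the replication clamp, stood at 140.0 and 82.2 FPKM. Mitochondrially encoded genes had a median of −0.56 (percentile 0.08), with MT-CYB at 137 and 76.0 FPKM, and 1 of 13 lower by 2-fold, MT-ATP8, of which 22.2% overlaps MT-ATP6 (2 of 13 with a pseudocount of 0.1, after rescaling or with size factors). Nuclear respiratory chain genes had a median of −0.31 (percentile 0.88) and 1 of 28 lower, COX4I1 at 136 and 57.3 FPKM. Mitosis genes lay inside the random range (−0.11, percentile 19.05; TOP2A alone of 28 lower), as did ribosomal proteins (−0.06, percentile 81.76; none of 56 past 2-fold).

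Several lists held members on both sides. In the hypoxia response (0.12, percentile 71.95; 3 of 28 higher, 2 lower), NDRG1 went from 38.5 to 97.4 FPKM and LDHA, the lactate dehydrogenase of glycolysis, from 566 to 205 FPKM. VEGFA and ANGPTL4 were the other higher members and CA9 the other lower one. At a minimum of 5 FPKM this list lay outside the random range (0.27, percentile 97.89). Mesenchymal transition and matrix genes had 3 of 23 higher and 6 lower, and their median of 0.25 (percentile 84.08) and mean of −0.06 differ in sign. CCN2 (48.1 and 11.7 FPKM) and THBS1 (38.7 and 10.9 FPKM), both matricellular proteins, were lower, and PLAUR, the urokinase receptor, was higher (16 and 42.5 FPKM). NF-kB and inflammation genes (0.14, percentile 52.16; 2 of 14 higher, 2 lower) included the iron-binding lipocalin LCN2 (2.03 and 22.1 FPKM) and the feedback inhibitor TNFAIP3 (11.3 and 3.86 FPKM), beside CXCL2 on the high and PTGS2 on the low side. Interferon-stimulated genes (−0.09, percentile 10.12, mean 0.07) had only IRF7 of 12 past 2-fold (3 higher and 2 lower with a pseudocount of 0.1), and AHR targets (−0.15, percentile 19.83) only CYP1A1 of 6. Hepatocyte secreted proteins had 5 measured members (0.76, percentile 96.36; 2 higher, APOE and APOC1), with APOE at 0.204 and 2.76 FPKM. Hepatocyte metabolism (−0.09, percentile 23.87, mean 0.13) had CEBPA higher (0.514 and 6.34 FPKM) and CPS1, of the urea cycle, lower (171 and 74.8 FPKM), of 6.

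Markers of cells outside the epithelium were few under the HepG2 label. Of 5 fibroblast and stellate markers, 2 were higher and 2 lower (median −0.97, percentile 0.01), ACTA2 (1.22 and 5.23 FPKM) and COL1A1 against PDGFRB (5.67 and 1.67 FPKM) and TAGLN; the call ended with no filter (percentile 16.42), at 5 FPKM (percentile 31.54) and by the mean (−0.12, percentile 5.64). Of the endothelial markers only TIE1 was measured, listed at 0 untreated and at 1.06 FPKM treated (1.04, percentile 86.74). Of 3 blood cell markers, the lysosomal glycoprotein CD68 was higher at 1.38 and 20.7 FPKM (0.70, percentile 88.06; 1.5, percentile 99.66, by the mean, and 3.19, percentile 99.78, at 5 FPKM).

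By single genes, the highest ratios in the libraries labelled HepG2 belonged to GGT1, a gamma-glutamyltransferase of glutathione turnover (0.094 and 35.0 FPKM), under an identifier absent from GENCODE 29, so its overlap is unknown. Next came AC004922.1, of which 47.8% overlaps the actin nucleation gene ARPC1B, and the cytokines IL24 (0.334 and 26.5 FPKM) and IL11 (0.962 and 35.3 FPKM). PCDH1, a protocadherin, went from 0.289 to 12.1 FPKM and CLDN4, a tight junction protein, from 4.85 to 49.4 FPKM. TMEM203 stood at 4.0 and 42.8 FPKM. Among the lowest ratios were TOMM6, of the mitochondrial import pore (68.4 and 5.73 FPKM), the CDC42 effector CDC42EP2 (8.73 and 0.323 FPKM), the TGF-beta receptor TGFBR1 (30.6 and 4.64 FPKM), ARPC5 of the Arp2/3 complex (57.1 and 9.38 FPKM) and endothelin EDN1 (12.2 and 1.72 FPKM). CA9, a hypoxia-induced carbonic anhydrase, stood at 4.23 and 0.054 FPKM, with 38.5% of it overlapping ARHGEF39. COMMD3-BMI1, ZBED6 and CORO7-PAM16 were also among the lowest, and each overlaps a neighbouring gene by 52.5% or more.

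In all, 794 of 11843 genes were at least 2-fold higher and 288 at least 2-fold lower in the treated library labelled HepG2. The median log2 ratio of all these genes was 0.087, and 95% of them lay between −0.99 and 1.37.

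Treated Huh7 cells had higher antioxidant, metal-binding and mitosis genes, lower DNA replication genes, and a lower median over secreted liver proteins. AKR1B10, an aldo-keto reductase driven by NRF2, went from 0.988 to 9.06 FPKM. MT1G, a metallothionein, went from 31.4 to 151 FPKM and HMMR, a spindle protein, from 4.78 to 21.9 FPKM. PCNA went from 202 to 79.7 FPKM. Of 33 measured NRF2 targets, 14 were at least 2-fold higher and none lower (median log2 ratio 0.95, percentile 100).

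In the metal and xenobiotic groups of Huh7, 5 of 7 metallothioneins were higher (median 1.19, percentile 100), MT1G, MT1M, MT1E, MT1F and MT2A (87.4 and 309 FPKM). AHR targets had 3 of 5 higher (1.04, percentile 99.99), but a median of 0.33 (percentile 97.22) with no filter. The higher ones were CYP1A1, an enzyme that oxidises aromatic compounds (17.3 and 48.8 FPKM), AHRR and UGT1A6. AHRR is uncertain, as its identifier is absent from GENCODE 29 and its overlap with other genes is unknown. UGT1A6 is uncertain too, as 36.5% of it overlaps UGT1A3. The aldo-keto reductases AKR1C1 (27.8 and 98.8 FPKM) and AKR1C2 (42.1 and 159 FPKM) were higher as well, uncertain because of near-identical copies. The heat shock response had 3 of 20 higher (0.41, percentile 99.89), HSPA1A, HSPA1B and HSP90AA1 (101 and 214 FPKM), but 0 of 20 with size factors and 5 of 20 with a pseudocount of 0.1. Stress programmes differed within the line: the ATF4 list had 4 of 32 higher, DDIT4, CHAC1, SLC3A2 and GDF15 (138 and 345 FPKM), with a median of 0.18 at percentile 97.63 that was inside the random range under 4 alternatives (percentile 95.53 to 97.29). Endoplasmic reticulum chaperones were lower (−0.29, percentile 0.98), with 2 of 21 past 2-fold, MANF (44.7 and 18.9 FPKM) and the translocon subunit SEC61B (116 and 50.7 FPKM). HSPA5, the main chaperone of that compartment and chosen after its values were seen, stood at 134 and 79.3 FPKM.

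Cell cycle genes split by phase in Huh7. Mitosis genes had 8 of 28 higher and none lower (median 0.67, percentile 100), including ASPM (1.82 and 9.78 FPKM) and the checkpoint kinase TTK (5.53 and 21.4 FPKM). DNA replication genes had 11 of 31 lower and none higher (−0.80, percentile 0.0), including the helicase subunit MCM3 (138 and 55.1 FPKM) and GINS2 (33.0 and 13.8 FPKM). Replication-dependent histones had a median of −0.47 (percentile 0.0) and a mean of −0.07 (percentile 52.35), since 3 of 28 were at least 2-fold higher. Of those, HIST1H2BG went from 0.267 to 40.3 FPKM and HIST1H2AC from 4.19 to 101 FPKM, the latter uncertain because a transcript antisense to it went from 31.9 to 0.829 FPKM and strand was not stated. HIST1H2AM was lower (167 and 7.92 FPKM), with 88.0% of it overlapping HIST1H3J. CDKN1A was lower, at 13.3 and 6.07 FPKM.

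Secreted liver proteins had 4 of 29 lower in treated Huh7 (−0.36, percentile 0.01), AFP, KNG1, the apolipoprotein APOC3 (33.7 and 14.2 FPKM) and the haem-binding HPX (36 and 16.2 FPKM). The list did not fall as a whole, though 0 members were higher by 2-fold. Other apolipoproteins rose short of that: APOE (268 and 414 FPKM) and, chosen after their values were seen, APOA2 (349 and 628 FPKM) and APOB (59.6 and 89.3 FPKM). Hepatocyte metabolism lay inside the random range (−0.09, percentile 15.62; none of 11 past 2-fold), with CEBPA at 229 and 228 FPKM. Inflammation genes under NF-kB had 2 of 13 lower (−0.43, percentile 0.18), NFKBIA and the chemokine CXCL1 (63.0 and 24.4 FPKM). Mesenchymal transition and matrix genes had a median of −0.34 (percentile 0.13) with none of 19 past 2-fold (3 lower with size factors, and 2 with a pseudocount of 0.1 or after rescaling), and THBS1 stood at 127 and 66.9 FPKM. The hypoxia response had 2 of 25 higher and 3 lower (−0.25, percentile 0.24). KDM3A and MXI1 were higher and LOX lower, as were LDHA (406 and 198 FPKM) and the glucose transporter SLC2A1 (12.7 and 4.53 FPKM), and the list lay inside the random range at a minimum of 5 FPKM (percentile 37.29). Interferon-stimulated genes lay inside the random range (0.26, percentile 76.11), with none of 9 past 2-fold, but 1 higher and 1 lower with a pseudocount of 0.1. Immediate early genes did too (−0.06, percentile 17.19, mean 0.12), with MYC alone of 14 higher. With a pseudocount of 0.1 or after rescaling 2 of the 14 were higher, and with size factors 1 was higher and 1 lower.

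Cholesterol synthesis in Huh7 had 3 of 25 higher (0.36, percentile 100), SC5D, IDI1 (19.7 and 64.9 FPKM) and HMGCS1 (189 and 380.0 FPKM), but 2 of 25 after rescaling each library to 1 sum and 1 of 25 with size factors. Autophagy and lysosome genes had a median of 0.40 (percentile 99.99) with none of 28 past 2-fold, and CTSB stood at 47.1 and 88.8 FPKM. Fatty acid synthesis (0.08, percentile 82.52; 1 of 16 higher, ACSS2, and 0 with size factors) and oxidation (0.01, percentile 43.05, mean −0.09; 1 of 19 lower, FABP1) lay inside the random range, and their medians were −0.04 and −0.10 with size factors. Mitochondrially encoded genes had a median of 0.37 (percentile 99.62) with none of 13 past 2-fold, and nuclear respiratory chain genes −0.29 (percentile 1.16) with none of 28. BCL2 family and caspase genes (0.13, percentile 58.82; none of 19, but 1 higher and 1 lower with a pseudocount of 0.1) and ribosomal proteins (−0.10, percentile 73.62; none of 56) lay inside. Of the marker lists, the 2 fibroblast markers measured, COL1A2 and LUM, were lower, with LUM at 31.7 and 8.05 FPKM (−1.51, percentile 0.02; percentile 18.55 with no filter), and no endothelial marker reached 1 FPKM. Of 4 blood cell markers, CD68 was higher (0.521 and 2.83 FPKM) and the endotoxin receptor CD14 lower (15.1 and 2.21 FPKM), with a median of −0.77 (percentile 0.06; percentile 39.3 with no filter).

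The highest single ratios in Huh7 were those of HIST1H3J (0.906 and 73.7 FPKM; 44.6% overlaps HIST1H2AM), HIST1H2BG and the uncertain HIST1H2AC, followed by TAX1BP3, a PDZ domain protein (2.3 and 50 FPKM). The choline transporter-like SLC44A2 went from 3.4 to 31.3 FPKM and the phosphatase DUSP15 from 0.248 to 8.01 FPKM. The lowest, after HIST1H2AM, were KTI12 (17.9 and 0.754 FPKM; 31.0% overlaps TXNDC12) and TMEM203 (36 and 3.08 FPKM). B3GALT6, a galactosyltransferase of proteoglycan synthesis, stood at 26.1 and 2.27 FPKM, and TXNDC5, a disulfide isomerase of the endoplasmic reticulum, at 204 and 25.4 FPKM. Also among the lowest were HIST1H2AD, ARPIN-AP3S2, AC117378.1 and AL135905.2, which overlap other genes by 61.6% or more, and CBSL, the copy of CBS.

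Of 11945 genes in Huh7, 464 were at least 2-fold higher (64.0% of those past 2-fold) and 261 at least 2-fold lower, with 95% of all ratios between −0.95 and 1.11. Median-ratio size factors shifted the median of all Huh7 genes by −0.10, and the split became 336 higher and 340 lower (49.7% higher).

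RENBP, TXNIP and FTL were among the genes higher in both lines, and ID1, ID3 and SMAD6 among those lower in both. RENBP, an N-acetylglucosamine epimerase, had log2 ratios of 2.2 in the libraries labelled HepG2 and 2.29 in Huh7. TXNIP, which binds thioredoxin, had ratios of 1.60 and 1.71, FTL of 1.58 and 1.66, and IDI1 of 1.41 and 1.67. MLXIPL, a glucose-sensing transcription factor, had ratios of 2.45 and 1.37, and the immune receptor TNFRSF14 of 1.73 and 1.75. On the low side, ID3 went from 67.3 to 16.3 FPKM and from 89.2 to 20.2 FPKM, and ID1 (ENSG00000125968; chromosome 20, 31605283 to 31606515) from 127 to 28.9 FPKM and from 676 to 218 FPKM. Both encode inhibitors of differentiation that BMP signalling induces.

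SMAD6, an inhibitory SMAD that BMP signalling also induces, stood at 22.7 and 9.01 FPKM and at 15.8 and 4.7 FPKM. ITM2B, a membrane protein processed to amyloid-type peptides, had log2 ratios of −1.72 and −1.92, the stress granule protein G3BP1 of −1.92 and −1.38, and SELENOF, a selenoprotein of the endoplasmic reticulum, of −1.48 and −1.75. OLR1, a receptor of oxidised LDL, had ratios of −1.30 and −2.03. CAPN5 and TSPAN8 were among the higher and lower genes as well, as were TUBA1A, NEIL1 and U2AF1, whose values are uncertain because of overlap or copies.

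Of 10758 genes at 1 FPKM or more in both lines, 77 were higher in both where independent lists would share 23.2, and 33 were lower in both where 4.3 would be shared. With size factors, 50 were higher in both (14.4 by independence) and 48 lower in both (6.6). Another 15 were higher in the libraries labelled HepG2 and lower in Huh7 (10.7 by independence), and 12 the reverse (9.3). The log2 ratios of the lines correlated across genes at r = 0.259 (rho = 0.29), with the same caution that genes are not independent.

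limma over the 4 libraries, with cell line as a block, called 0 of 13030 genes at an adjusted p under 0.05, and 1041 higher and 493 lower at an unadjusted p under 0.05 (785 and 717 with size factors). FTL came nearest (log2 ratio 1.62, SE 0.147, limma adjusted p = 0.0817; higher in both lines), followed by ID3 (−2.03, SE 0.217, limma adjusted p = 0.119) and ID1 (−1.86, SE 0.208, limma adjusted p = 0.119), lower in both. FTH1 (1.43, SE 0.203), HMOX1 (1.58, SE 0.229) and CHAC1 (2.39, SE 0.469) had limma adjusted p of 0.166, 0.166 and 0.212, TFRC (−0.80, SE 0.204) of 0.259 and GPX4 (−0.46, SE 0.211) of 0.447. FTL passed limma at a minimum of 5 FPKM (adjusted p = 0.0326), and FTL, ID1 and ID3 passed it with size factors (adjusted p = 0.0456, 0.0491 and 0.0491). No gene passed limma in the other alternatives, whose smallest adjusted p was 0.061 to 1.0.

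**Figure D3:**
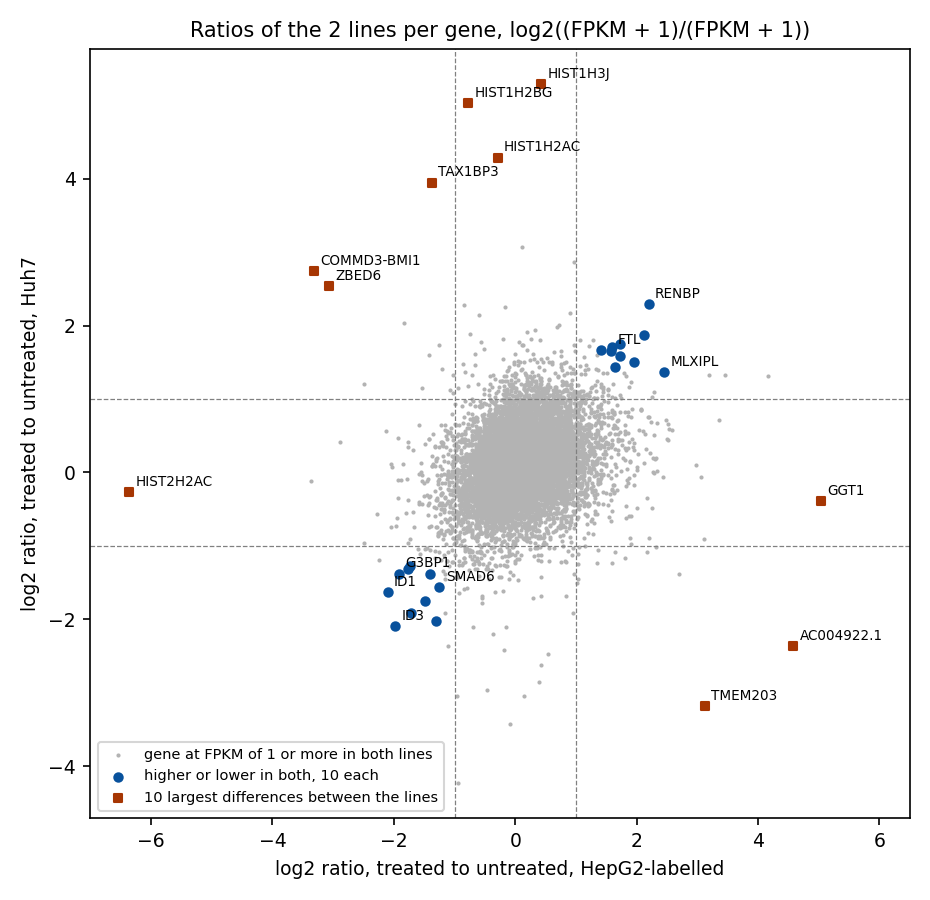
Log2 ratio of treated to untreated FPKM + 1 in the libraries labelled HepG2 (horizontal) and in Huh7 (vertical), 1 grey point per gene at 1 FPKM or more in both lines, with dashed lines at 2-fold. Blue points are the 10 genes highest and 10 lowest in both lines, and red squares the 10 genes that differ most between the lines, where the difference was not tested.

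Of the gene lists, 15 of 30 lay outside the random range in the libraries labelled HepG2 and 20 of 29 in Huh7. Lists outside it on the same side in both lines were NRF2 targets, the ATF4 list, cholesterol synthesis, metallothioneins and autophagy and lysosome on the high side. Of these, the ATF4 list in Huh7 lay inside the range under 4 alternatives (percentile 95.53 to 97.29), and with no filter so did NRF2 targets (percentile 97.39) and metallothioneins (percentile 49.29) under the HepG2 label. DNA replication, histones, nuclear respiratory chain genes and fibroblast markers were so on the low side. Histones in Huh7 lay inside the range by the mean (percentile 52.35). Fibroblast markers, with 5 and 2 measured members, lay inside it with no filter in both lines (percentile 16.42 and 18.55), and under the HepG2 label also at 5 FPKM (percentile 31.54) and by the mean (percentile 5.64). Endoplasmic reticulum chaperones and mitochondrially encoded genes lay outside on opposite sides.

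**Figure D4:**
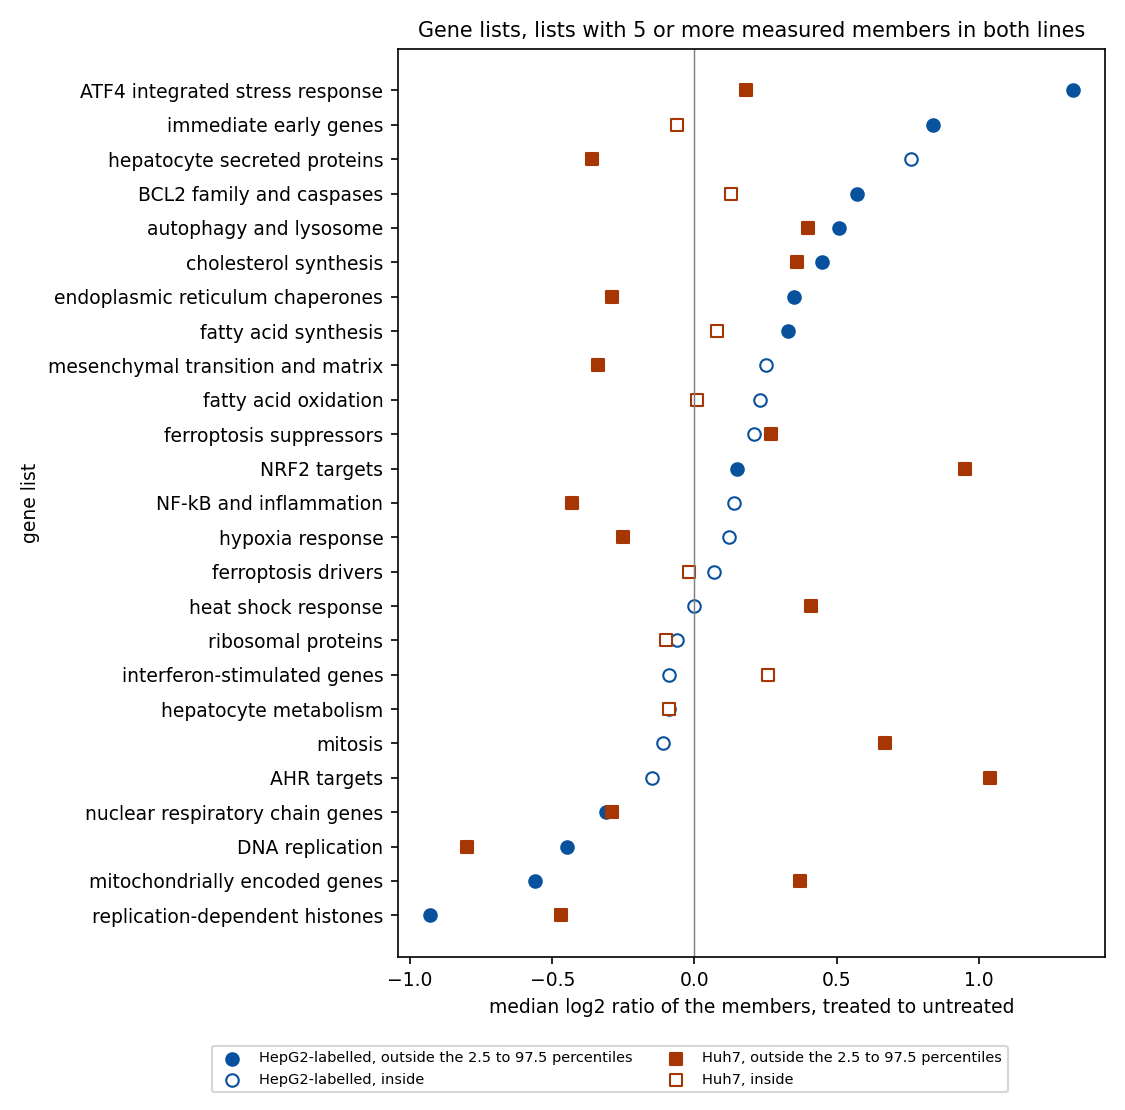
Median log2 ratio of treated to untreated FPKM + 1 over the measured members of 25 gene lists with 5 or more measured members in both lines. Filled symbols lie outside the random range; the ATF4 list stands at 1.33 in the libraries labelled HepG2 and at 0.18 in Huh7, the latter inside that range under 4 alternatives.

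Among long noncoding transcripts, LINC00958 was higher and MALAT1 lower in the treated cells labelled HepG2, and a transcript over the ribosomal protein gene RPS29 was higher in treated Huh7. LINC00958-201 went from 3.17 to 34.2 FPKM in the libraries labelled HepG2 and stood at 5.52 and 5.27 FPKM in Huh7. MALAT1-202, of a nuclear retained RNA, went from 50.2 to 6.71 FPKM under the HepG2 label and from 19.9 to 49.4 FPKM in Huh7, and MALAT1-201 from 17.2 to 1.03 FPKM under the HepG2 label. AC016888.1-201 was listed at 0 untreated and at 17.4 FPKM treated there. RPS29-OT1 stood at 0.605 and 123 FPKM in Huh7, and LINC1120 at 4.2 and 28.0 FPKM. A transcript antisense to HIST1H2AC (ENSG00000180573-AS2) was lower in both lines, at 66.2 and 7.13 FPKM and at 31.9 and 0.829 FPKM. Strand was not stated, so reads of such transcripts cannot be told from those of the genes they overlap. In all, 178 of 1315 transcripts were at least 2-fold higher and 69 lower in the libraries labelled HepG2, and 159 of 1548 higher and 85 lower in Huh7. Of 657 transcripts measured in both lines, 19 were higher in both (5.4 by independence) and 6 lower in both (1.0), with r = 0.277 and rho = 0.297 across transcripts, which are not independent replicates. Signal recognition particle RNA (RN7SL) made up 93.2% to 94.5% of the summed FPKM of this table.

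In the authors' deposited table for cells labelled HepG2, 635 of 12517 Gene Ontology terms had a corrected p under 0.05, led by intrinsic to plasma membrane (436 of 1878 genes, corrected p = 7.61e-20) and system development (960 of 5060 genes, corrected p = 2.42e-19). Nucleosome, with 38 of 114 genes, had a corrected p of 2.72e-08 in the authors' deposited table, and by FPKM 3 of the 38 were higher and 35 lower after treatment. For Huh7, the authors' deposited table had 381 of 11546 terms under 0.05, including ion transport (282 of 1654 genes, corrected p = 1.44e-09) and extracellular matrix (101 of 406 genes, corrected p = 2.63e-10). Of the 101 matrix genes, 28 were higher and 73 lower by FPKM, and of the 38 that reached 1 FPKM, 3 were at least 2-fold higher and 13 lower. Of 9952 terms in the authors' deposited tables of both lines, 243 were under 0.05 in both, where independent lists would share 24.1, though terms are nested and so not independent. For KEGG, the authors' deposited table had none of 275 pathways under 0.05 for cells labelled HepG2, where Alcoholism, a pathway that holds many histone genes, came first (60 of 180 genes, corrected p = 0.0651; 18 higher and 42 lower by FPKM). For Huh7, the authors' deposited table had 1 of 271, steroid hormone biosynthesis (26 of 57 genes, corrected p = 0.00175). Of the 26, 11 were higher and 15 lower by FPKM, and of the 9 that reached 1 FPKM, 5 were at least 2-fold higher and 0 lower. The gene lists behind the authors' deposited tables of Gene Ontology terms held 3213 and 2438 genes, of which 1470 and 1052 reached 1 FPKM, 598 and 289 were at least 2-fold higher, and 255 and 235 at least 2-fold lower.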

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

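The tests of shared sequence and of the ATF4 list were chosen after the result was seen, and that of low expression before. None of the differences between the lines given here was tested, as each line has 1 library per group.

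Endoplasmic reticulum chaperones and mitochondrially encoded genes were the lists outside the random range on opposite sides in the 2 lines. Chaperones were higher in the treated library labelled HepG2 and lower in treated Huh7, a difference of the medians of 0.64. Mitochondrially encoded genes went the other way, with a difference of −0.93. CDKN1A, which halts the cell cycle, was higher in the cells labelled HepG2 and lower in Huh7 by at least 2-fold each, a difference of 3.33. TGFBR1, the TGF-beta receptor kinase, differed by −3.69 and TAX1BP3 by −5.33, lower under the HepG2 label and higher in Huh7. AC004922.1 differed by 6.94 and TMEM203 by 6.31, higher under the HepG2 label and lower in Huh7, and COMMD3-BMI1 by −6.07 and ZBED6 by −5.61, the other way.

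The genes whose log2 ratios differed by 2 or more between the lines numbered 108 of 10758. Low expression stays open: the median of their highest FPKM was 26.3, against 15.8 for all genes, but a set chosen by a ratio with a pseudocount favours such values, and HIST1H2BG, for example, stood at 0.267 FPKM in untreated Huh7. Reads shared between overlapping genes or near-identical copies may account for part of them. Of the 108, 24 share exons or sequence, 22.2% (exact 95% interval 14.8 to 31.2) against 7.9% of all genes, among them AC004922.1, COMMD3-BMI1 and ZBED6. TMEM203, TGFBR1, TAX1BP3 and CDKN1A share less than these thresholds, and a difference between the cell types stays open, untested.

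The ATF4 list was higher in the libraries labelled HepG2 than in Huh7, by 1.15 between the medians. Under the other scalings the difference was 1.21 and 1.26. Each applies 1 factor per library and shifted the median of a line by −0.103 to 0.05, too little to remove the difference. The outcome was thus fixed in advance, and other forms of scaling were not tested. A higher untreated level of these genes in Huh7 stays open. Over 32 members the median log2 ratio of untreated Huh7 to untreated HepG2-labelled cells was 0.53, against −0.08 for all genes. Both untreated libraries also enter the difference to be explained. Low values in the untreated library labelled HepG2 would raise both, so the ratio cannot decide. ASNS, for example, stood at 134 FPKM in untreated Huh7 and 27.4 in the untreated library labelled HepG2. A different response of the cell types stays open.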

How the results depend on the processing

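All alternatives here were planned. With 1 library per group, depth limits low genes: 1 FPKM over 1 kb rests on 23 or 26 fragments, so ratios near that level are imprecise. No replicate could be left out, and leaving out 1 cell line leaves limma no residual degree of freedom, so it gave no value. Without the libraries labelled HepG2, the Huh7 counts stand alone, and neither agreement nor limma can be computed. Counts and correlations stayed within 1.5 times, or near their value, in 54 cases and moved in 51. Ratios of named genes stayed in 586 cases and moved in 299. Of the gene lists, 334 kept their direction and side of the random range, 13 no longer lay outside it, 4 came to lie outside it and 2 turned.

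Under the 1.5-fold rule, which by construction counts more genes, 2277 were higher and 1038 lower in the libraries labelled HepG2, and 1841 and 912 in Huh7. There 503 were higher in both lines, 205 lower in both and 147 opposite, and long noncoding transcripts numbered 421 higher and 143 lower under the HepG2 label, and 408 and 170 in Huh7. Under the 4-fold rule, which counts fewer, 68 were higher and 18 lower under the HepG2 label, and 21 and 28 in Huh7. RENBP was the 1 gene higher in both, 0 were lower in both, and 4 were opposite (AC004922.1, TMEM203, COMMD3-BMI1 and ZBED6). Long noncoding transcripts then numbered 13 and 12 under the HepG2 label, and 12 and 10 in Huh7.

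A pseudocount of 0.1, which by construction widens the ratios of low genes, gave 1331 genes higher under the HepG2 label, and 970 higher and 422 lower in Huh7. It gave 194 higher in both, 54 lower in both and 47 opposite, and long noncoding transcripts of 417 higher and 133 lower under the HepG2 label and 408 and 164 in Huh7. Of the lists, it gave 5 of 21 higher in the BCL2 family and caspases and 5 of 14 lower in NF-kB and inflammation under the HepG2 label, and 3 of 4 blood cell markers lower in Huh7. Rescaling to a sum of 1000000, which makes the pseudocount smaller beside the values, gave 1280 higher under the HepG2 label and 700 higher in Huh7. It gave 142 higher in both and 43 opposite, and long noncoding transcripts of 408 higher and 136 lower under the HepG2 label and 333 and 200 in Huh7.

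A minimum of 5 FPKM, which leaves fewer features, gave 29 higher and 15 lower long noncoding transcripts under the HepG2 label and 25 and 10 in Huh7. It moved the correlation of the lines to r = 0.288, and no filter moved it to r = 0.222. With no filter the metallothionein median under the HepG2 label was 0.0, as 4 of the 9 members then counted are listed at 0 in both libraries. With size factors 50 genes were higher and 48 lower in both lines, and limma called 3 genes (FTL, ID1 and ID3), against 1 (FTL) at a minimum of 5 FPKM. The cause was not tested. By the mean, the Huh7 histone list stood at −0.07, on the other side of the random median, as 3 members were much higher. A corrected p under 0.01, stricter by construction, left 390 terms for cells labelled HepG2 and 208 for Huh7 in the authors' deposited table. Without the cell line block, limma called 0 genes, with 62 higher and 50 lower at an unadjusted p under 0.05, so the count of 0 was the same with and without it.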

Other observations

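The tests of the HepG2 label were chosen after the result was seen. Those of BMP-SMAD and YAP targets were set before their other members were looked at.

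Of the ribosomal protein transcripts, RPS19 was higher in both lines, short of 2-fold, at 578 and 939 FPKM in the libraries labelled HepG2 and at 801 and 1319.7 FPKM in Huh7, and RPS6 stood at 791 and 466 FPKM and at 474 and 427 FPKM. RPS29, outside the list measured and chosen after its values were seen, stood at 2879 and 1601.4 FPKM under the HepG2 label and at 1604.8 and 7810.6 FPKM in Huh7. The ATP synthase subunit ATP5MC1 was lower in both lines, at 94.1 and 51.7 FPKM and at 81.6 and 47.9 FPKM.

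Hepatocyte secreted transcripts were near 0 in both libraries labelled HepG2. Failed quantification at these genes in every library is argued against, since their median in untreated Huh7 of the same table was 33.7 FPKM. A single library exchanged between the lines is argued against as well, since the lower of the medians of the Huh7 libraries was 20 FPKM. That value does not bear on an exchange of all 4, which would only move the absence to the Huh7 label. The Huh7 levels were seen before these tests were chosen, so the tests restate that contrast and add no separate evidence. Cells other than HepG2 stay open: ALB, AFP, TF, FGA, FGB and FGG, 6 of 6 transcripts known as abundant in HepG2, were below 1 FPKM in both libraries, but they belong to the list that raised the question, so the count decides nothing. A subline that lost hepatocyte identity stays open too, with no reference profile used here.

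ID1, ID3 and SMAD6 were lower in both lines, and a hypothesis is that BMP-SMAD target expression was lower. Other members of a target list were lower too, with medians of −0.79 over 6 genes in the libraries labelled HepG2 and −1.22 over 5 in Huh7, and the higher of the percentiles was 0.02. ID2 stood at 6.85 and 3.15 FPKM and at 81.9 and 33.7 FPKM, and SMAD7 at 14.7 and 6.74 FPKM and at 15.9 and 6.23 FPKM. MSX1 went the other way under the HepG2 label, at 2.83 and 7.2 FPKM. The result is consistent with the hypothesis but does not show which step of the pathway differed.

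CCN1, CCN2 and THBS1 were lower in the treated library labelled HepG2, and a hypothesis is that YAP target expression was lower. The other 17 members of a target list had a median of −0.26 there, at percentile 1.03, and 14 in Huh7 had −0.15, at percentile 4.31. ANKRD1 stood at 5.05 and 1.61 FPKM and NT5E, against the direction, at 11.7 and 33.0 FPKM under the HepG2 label. The test is consistent with a small shift, as 1 of the 17 was lower by 2-fold and 1 higher, and 3 of the 14 in Huh7 were lower (IGFBP3, CCDC80 and NUAK2) and 0 higher.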
